A study of Rattus norvegicus with 50 samples.

How the data were processed

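Lung tissue of 50 male rats was profiled on Agilent 2-colour expression arrays, 1 array per animal, in 10 groups of 5 animals. Per the labels, total RNA of each lung carried the dye Cy5 and a common reference RNA carried Cy3. The labels name the reference once as a rat and once as a mouse product, and they name 2 different stocks of Wistar rats, so neither is stated further here.

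The scanner files were made by the authors with Agilent Feature Extraction 11.0.1.1, per the file headers. Per the file headers, the median signals of each spot and of its local background are intensity values with no normalization. The deposited processed signals are intensity values that Feature Extraction had background-subtracted, detrended across the array and dye-normalized. Other deposited columns hold marks that the software set for each spot, such as control spots and spots well above background. The deposited series table holds ratios of Cy5 over Cy3, read here as log2 and normalized by the authors so that each array centres near 0. The scale of that table is not named in the labels. Its array medians lay between -0.034 and 0.0029, which holds for centred ratios in any log base. The table holds 30367 probes, and its values correlated with those computed here at r between 0.996 and 0.999 per array, across probes.

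The scanner files were read in R 4.3.3 with the package data.table (version 1.17.8) and analysed with limma 3.58.1. Each array held 62976 spots, of which 58717 were not controls, and these belonged to 30367 probes. Background was corrected with limma's normexp method with an offset of 50, followed by loess within each array with control spots given no weight. Spots of a probe were averaged, leaving out spots that the software had marked as non-uniform or as outliers; 70 probe values came from marked spots alone. The files hold no mean signal columns, so median signals took the place of the mean signals named in the design fixed before the data were examined. No scaling was applied between arrays. Probes were kept when Cy5 was well above background on at least 4 of the 5 arrays of at least 1 group, which left 20291 probes. One probe stood for each gene, the brightest on average, which left 17831 genes.

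Gene names came from the RefSeq accession of each probe, matched to an annotation table of the GRCr8 assembly. The headers give probe positions on an older build, so the table served for names alone and no coordinates are given. Names were found for 18643 probes (61.4%), and 11724 probes stayed unmatched. Of the genes tested, 11577 had a symbol.

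Brightness sets the precision of an array. The median Cy5 signal per array ran from 115.5 to 322 intensity units, that of Cy3 from 139 to 208, and between 62.1% and 74.4% of spots were well above background in Cy5. No spot was saturated (0 spots), and 5 animals per group limit the precision of each mean. The arrays lay on 7 slides scanned on 4 days.

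All groups entered 1 linear model in limma with moderated variances and an intensity trend, and p-values were adjusted by Benjamini-Hochberg over all genes of a comparison. Genes were called at an adjusted p under 0.05, and the count with a fold of at least 1.5 is given beside it. Exposed groups were compared with air of the same day, the coatings with each other at the lower and at the higher dose, the doses within a coating, and the days with each other. Air animals were shared between comparisons, so overlaps were also computed with the air animals divided between them and in 20 simulations of unchanged groups. The design, the alternatives, the rule for named genes and 39 gene lists of 800 symbols, 665 of them measured, were fixed before the data were examined. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, then with an estimated correlation and with fry. Of 177 list calls, 8 held with the estimated correlation.

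By the rule for named genes, the 10 largest rises and 10 largest falls were taken for each exposed group against air, and 5 of each elsewhere, among genes with a symbol that passed the test, were above background where they were higher and moved alike in all 5 animals. From each list, up to 4 members past the test were named, or the brightest 1 or 2 where none passed. Where a gene was not well above background on any array of a group, the text gives a bound ("at least"). Bounds were taken from the Cy5 channel alone after loess and Aquantile scaling, with the dim group at no less than the lowest signal well above background. They are open to dye bias and can differ from the fold of the ratios in either direction. Values are log2 fold changes with the standard error of the model unless stated otherwise, with 5 animals in each group.

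The pipeline was tested on simulated data, in which known fold changes were given to chosen genes of simulated libraries. At 1.5-fold, 82% of 50 changed genes were called, at 2-fold 92%, and at 4-fold and 8-fold 100%. Among 17588 genes left unchanged, 12 were called (5.66% of all calls), and a comparison in which nothing had been changed gave 0 calls. These shares hold for the simulated libraries alone and are not error rates of the real ones. Splits of the real animals, given below, called up to 8919 genes.

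Alternatives tried were Agilent's processed signals, the deposited series table, the Cy5 channel alone, centring and Aquantile scaling between arrays, no filter or a stricter filter on background, every probe kept, array weights, slide as a fixed or random block, scan day as a block, only the compared groups in the model, a fold threshold, and leaving out each animal. Aquantile scaling leaves the ratio of the dyes as it is, so it tested nothing here. Chosen after seeing the data were a fit without 2 libraries and a fit with Cy5 brightness as a covariate. The libraries left out are labelled Air animal 1 and PEI 8.6 animal 61, both of day 6. ASC animals are cited with the letter that their labels put before the number. Figures were drawn with matplotlib.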

Results

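Lungs were collected from rats that had breathed air or an aerosol of copper oxide nanoparticles through the nose on consecutive days. The particles carried either a positively charged coating labelled PEI or a negatively charged coating labelled ASC. Doses are 6-hour equivalents of 3 and 8.6 mg per cubic metre for PEI and of 3.8 and 10.9 mg per cubic metre for ASC. Lungs were taken at study day 6, which was 1 day after the last exposure, and at day 27, which was 22 days after it. Each of the 10 groups held 5 animals, and air animals were present on both days. Expression was measured as the log2 ratio of the lung sample to a common reference, and the median Cy5 signal of the arrays ran from 115.5 to 322 intensity units.

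The first principal component held 41.7% of the variance and set most exposed lungs of day 6 apart from all other lungs. Mean scores at day 6 were 18.8 for PEI 3, 25.3 for PEI 8.6, 22.8 for ASC 3.8 and 36.4 for ASC 10.9, and all groups of day 27 had means between -22.9 and -13.4. A pair of libraries of day 6 stood with another group than their own. The library labelled Air animal 1 scored 36.2 where the other air libraries lay between -31.2 and -15.6, and the library labelled PEI 8.6 animal 61 scored -32.6 where the others of its group lay between 28.3 and 45.9. Their labels were kept, and the count of called genes in each comparison is also given without both. Overlaps, counts of list members and list tests with an estimated correlation are given with both included. Their distance from their groups enters that estimate, which was taken over all groups together. A list that did not hold, at day 6 or in any other comparison, may therefore still have moved.

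**Figure D1:**
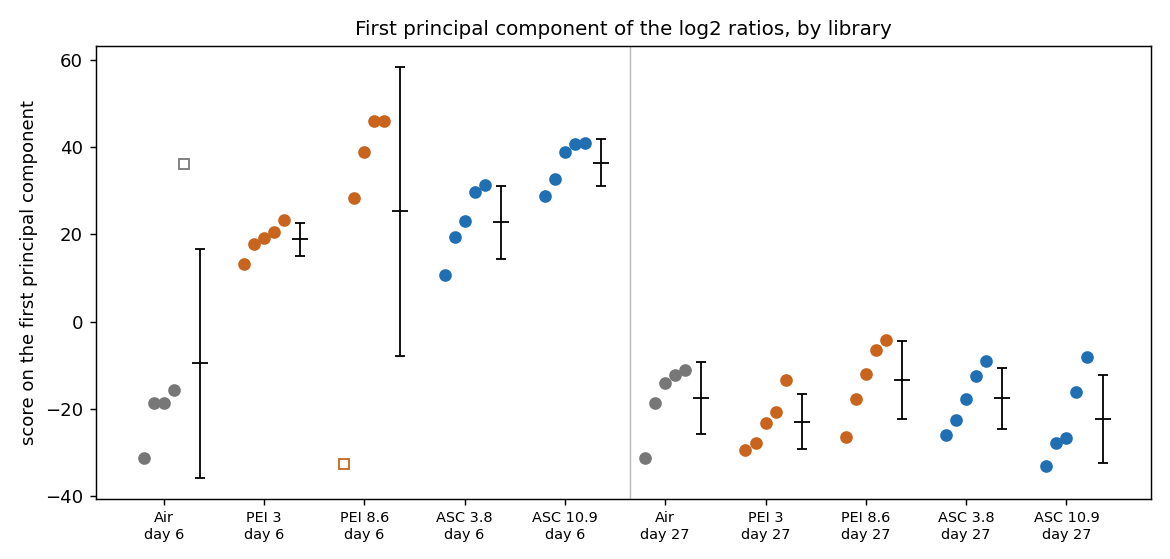
Score of each library on the first principal component of the log2 ratios (vertical axis, no unit) by group and study day, with group means and SD as bars. Open squares are the libraries labelled Air animal 1 (36.2) and PEI 8.6 animal 61 (-32.6), which lie away from the rest of their groups.

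The lower dose of PEI was compared with air at day 6 to ask what the positively charged particles changed shortly after exposure. Mmp12, an elastase of macrophages, rose 6.44-fold (log2 2.69 ± 0.44, SE, n = 5 per group), and Orm1, an acute phase protein, rose 6.74-fold (2.75 ± 0.46). The chemokines Ccl22 (2.16 ± 0.31) and Ccl17 (2.04 ± 0.35), the anion exchanger Slc26a4 (2.33 ± 0.48) and the complement regulator C4bpa (2.02 ± 0.45) rose too, each in 5 of 5 animals. Of 24 measured genes of cholesterol synthesis 19 rose, among them Idi1 (2.74-fold), Acat2 (1.28 ± 0.23) and Hmgcs1 (1.19 ± 0.18), and none fell. Of 44 cell cycle genes 19 rose, with Rrm2 higher 2.82-fold, Ect2 at 1.42 ± 0.29 and the proliferation marker Mki67 at 1.25 ± 0.27. Falls included Pla2g2d, a secreted phospholipase (-1.57 ± 0.30), the cholesterol exporter Abcg1 (-1.21 ± 0.29), and the neuropeptide precursor Tac1, which was not well above background in PEI 3 lungs (2.32-fold lower by the ratios, at least 2.38-fold by the Cy5 channel).

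Adjusted over the list alone, 22 cholesterol synthesis genes and 34 cell cycle genes were higher in PEI 3 lungs. Camera called both lists up, at adjusted p = 2.9e-27 and 2.4e-22, but adjusted p = 0.069 and 0.33 with an estimated correlation. The acute phase list (6 of 25 rose, 11 rose and 1 fell over the list alone, camera adjusted p = 3.8e-05) and the cytokine list (8 of 37 rose, 11 over the list alone, 0.0002) were also called up, each at adjusted p = 0.33 with an estimated correlation. Among cell type lists, camera called macrophage (mean 0.51; 2 of 22 rose, 10 over the list alone; adjusted p = 3.8e-05) and neutrophil markers (0.43; 3 of 17 rose, 5 rose and 1 fell over the list alone; 0.0045) up. It called alveolar type 1 (-0.32; 0 of 11 fell, also over the list alone; 0.00049), endothelial (-0.22; 0 of 17, also over the list alone; 0.0045) and mesothelial markers (-0.79; 2 of 4 fell, 4 over the list alone; 8.2e-05) down. With an estimated correlation none held (adjusted p = 0.33, 0.33, 0.33, 0.57 and 0.14). Without Air animal 1 the means were 0.74 for macrophage, -0.47 for alveolar type 1 and -0.38 for endothelial markers. Of 13 genes of the circadian clock 1 rose (Dbp, an output of the clock, 2.58-fold), and 2 fell (Bmal1, -0.56 ± 0.13, and Cry1, -0.59 ± 0.14). Over the list alone 2 rose and 3 fell. Camera did not call that list (adjusted p = 0.51, 0.76 with the estimated correlation). Of 39 lists, camera called 9 up and 7 down for PEI 3, and 0 held. Within slides that held both groups, the cell cycle mean differed by -0.29 to 0.90 and was higher on 3 of 4 slides, and within scan days it differed by 0.30 to 0.84. Each of these slides held a single library per group, and the air library of slide 1 was Air animal 1. In limma, 566 genes passed (430 higher, 136 lower), 243 of them with a fold of at least 1.5, and 4349 passed without the libraries Air animal 1 and PEI 8.6 animal 61. The count was 3429 without Air animal 1, between 129 and 183 without any other single air animal (2, 3, 4 or 5), 299, 295 and 316 without PEI 3 animals 47, 48 and 49, 895 with scan day as a block, and 0 when only these groups entered the model.

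The higher dose of PEI at day 6 was compared with air for the same question. The calprotectin genes S100a8 and S100a9 rose by log2 2.24 ± 0.41 and 2.17 ± 0.40 (n = 5 per group), the serine protease gene Prss30 by 2.90 ± 0.69 and the neutrophil attractant Cxcl1 by 1.44 ± 0.34, in 5 of 5 animals. Mmp12 (2.37 ± 0.44), Orm1 (2.49 ± 0.46) and the monocyte attractant Ccl2 (2.74 ± 0.59) rose with 4 of 5 animals above the air mean. Interferon response genes rose in 15 of 27 cases, with Cxcl10 at 2.12 ± 0.58, Rsad2 at 1.69 ± 0.44 and Ifit3 at 1.68 ± 0.45. The cystine transporter Slc7a11, a target of the oxidative stress regulator NRF2, rose by 1.57 ± 0.33. Naaa, an amidase (-1.35 ± 0.29), the glucocorticoid-induced Tsc22d3 (-1.13 ± 0.26) and the fibroblast marker Inmt (-1.11 ± 0.24) fell.

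Of the 44 cell cycle genes 36 rose in PEI 8.6 lungs (39 adjusted over the list alone), Ect2 by 1.56 ± 0.29, and of the 24 cholesterol synthesis genes 20 rose (22 over the list alone), Idi1 by 1.23 ± 0.21. Among 11 markers of alveolar type 1 cells 5 fell (10 over the list alone), Vegfa by 0.73 on the log2 scale. Of 17 endothelial markers 2 fell (7 over the list alone), and of 37 cytokine genes 14 rose and 1 fell (19 and 1 over the list alone). Camera called the cell cycle list (adjusted p = 5.2e-23), cholesterol synthesis (2.9e-15) and interferon response (9.7e-07; 18 over the list alone) up, and endothelial (1.4e-05) and alveolar type 1 markers (2.2e-05) down. With an estimated correlation none held (adjusted p = 0.31, 0.31, 0.47, 0.38 and 0.38). Macrophage markers were called up too (mean 0.57; 7 of 22 rose, 13 rose and 1 fell over the list alone; adjusted p = 0.00014, and adjusted p = 0.44 with an estimated correlation). Camera also called neutrophil markers (0.57, 8 of 17 rose and 1 fell, also over the list alone, adjusted p = 0.0011) up and fibroblast markers (-0.39, 5 of 13 fell, also over the list alone, adjusted p = 0.00036) down. With the estimated correlation these were adjusted p = 0.38 and 0.31. For PEI 8.6 camera called 7 lists up and 6 down, and 0 held. Within slides the cell cycle mean differed by -0.01 to 1.18, higher on 2 of 3 slides, and within the 2 scan days that held both groups by 0.58 and 0.65. Each of these slides held a single library per group. The air library of slide 1 was Air animal 1, and the PEI 8.6 library of slide 5 was PEI 8.6 animal 61. Both also enter the scan day values, so these ranges depend on them.

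In limma, 2494 genes passed for PEI 8.6 at day 6 (1589 higher, 905 lower; 694 with a fold of at least 1.5). Without the libraries Air animal 1 and PEI 8.6 animal 61 the count was 7744, of which 2486 were called in both fits, and log2 changes were 1.53 times as large in the median. Leaving out single libraries gave 5484 without Air animal 1 and 6111 without PEI 8.6 animal 61, but 942, 1089, 857 and 1226 without Air animals 2, 3, 4 and 5, and 1624, 1045, 1164 and 850 without PEI 8.6 animals 57, 58, 59 and 60. With only these groups in the model 0 genes passed.

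The lower dose of ASC asked what the negatively charged particles changed at day 6. Mmp12 rose 7.58-fold (log2 2.92 ± 0.44, n = 5 per group), Orm1 7.11-fold (2.83 ± 0.46) and Ccl22 by 2.11 ± 0.31, in 5 of 5 animals. The phagocyte receptor genes Trem2 (1.76 ± 0.28) and Lilrb4 (2.11 ± 0.41) rose, as did 12 of 22 macrophage and monocyte markers (14 adjusted over the list alone). Among genes of the circadian clock Dbp rose 17.5-fold (4.13 ± 0.27), and the clock activators Bmal1 (-2.05 ± 0.13) and Npas2 (-1.80 ± 0.14) fell. Of 19 heat shock and unfolded protein response genes 11 fell, among them the chaperones Hspb1 (-1.06 ± 0.18), Hspa5 (-1.01 ± 0.15) and Hsp90aa1 (-0.69 ± 0.11). Other falls were those of Cyp26b1, which degrades retinoic acid (-1.99 ± 0.28), Fibin (-1.71 ± 0.18) and Spon2 (-1.62 ± 0.24).

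In ASC 3.8 lungs 35 of 44 cell cycle genes rose (37 adjusted over the list alone; Ect2 1.76 ± 0.29), and 23 of 24 cholesterol synthesis genes rose (23 over the list alone; Fdps 1.39 ± 0.29). Of 13 clock genes 7 rose and 4 fell, the same numbers as over the list alone; camera called the list up at adjusted p = 0.039, but adjusted p = 0.33 with an estimated correlation and adjusted p = 0.16 without the libraries Air animal 1 and PEI 8.6 animal 61. Camera gave adjusted p = 2e-19 for the cell cycle, 6.3e-16 for cholesterol synthesis, 3.2e-07 for macrophage markers and 7.1e-07 for the heat shock list (1 rose and 11 fell over the list alone). With an estimated correlation these were adjusted p = 0.33, 0.30, 0.33 and 0.050. Called down were alveolar type 1 (mean -0.25, 1 of 11 fell, 1 rose and 3 fell over the list alone, adjusted p = 0.049), endothelial (-0.25, 2 of 17 fell, also over the list alone, adjusted p = 0.013) and fibroblast markers (-0.26, 2 of 13 fell, 5 fell over the list alone, adjusted p = 0.023). With the estimated correlation these were adjusted p = 0.60, 0.60 and 0.37. Without Air animal 1 these means were -0.40, -0.41 and -0.33. In all, camera called 9 lists up and 5 down, and 0 held. Cell cycle means were higher on 3 of 3 slides that held both groups, by 0.10 to 0.99. Each of these slides held a single library per group, and the air library of slide 1 was Air animal 1. In limma 2830 genes passed (1730 higher, 1100 lower; 684 with a fold of at least 1.5) and 6037 without the libraries Air animal 1 and PEI 8.6 animal 61. The count was 5302 without Air animal 1, 1781 and 1683 without Air animals 4 and 5, 1674 without ASC 3.8 animal L104, and 935 with only these groups in the model.

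The higher dose of ASC was compared with air at day 6 in the same way. Lcn2, an iron-binding antimicrobial protein, rose 37.1-fold (log2 5.21 ± 1.32, n = 5 per group), the complement factor Cfi by 3.05 ± 0.50, Mmp12 by 3.04 ± 0.44, the chemokine Ccl12 by 3.04 ± 0.61 and Spp1, which encodes osteopontin, by 2.85 ± 0.52, each in 5 of 5 animals. Of 27 interferon response genes 19 rose and 1 fell, with Mx1 at 1.96 ± 0.51. Among 26 metal handling genes 9 rose and 4 fell, with metallothionein Mt1 at 1.48 ± 0.41, and of 27 NRF2 genes 10 rose and 2 fell, with Slc7a11 at 1.58 ± 0.33. Dbp (4.12 ± 0.27), Bmal1 (-2.19 ± 0.13) and Npas2 (-2.22 ± 0.14) moved as they had at the lower dose. The chemokine gene Cxcl14 (-2.10 ± 0.35), Pla2g2d (-2.05 ± 0.30) and the endothelial gene Esm1 (4.01-fold lower) fell.

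In ASC 10.9 lungs 40 of 44 cell cycle genes rose (40 adjusted over the list alone), Ect2 by 2.13 ± 0.29 and Cdk1 3.99-fold, and 22 of 24 cholesterol synthesis genes rose (22 over the list alone). Macrophage and monocyte markers rose in 15 of 22 cases (15 over the list alone), and 7 of 17 endothelial markers fell (10 over the list alone), among them Kdr (-0.81 ± 0.24). Over the list alone 11 metal handling genes rose and 5 fell, and 13 NRF2 genes rose and 4 fell; camera called neither list (adjusted p = 0.26 and 0.12). Camera gave adjusted p = 1.2e-21 for the cell cycle, 2.5e-10 for cholesterol synthesis, 1.8e-06 for macrophage markers, 0.0001 for the interferon response (19 rose and 1 fell over the list alone) and 0.00031 for endothelial markers. With an estimated correlation the values were adjusted p = 0.36, 0.36, 0.36, 0.60 and 0.60. The clock list was also called up (mean 0.47, 7 of 13 rose and 3 fell, also over the list alone, adjusted p = 0.035) and the heat shock list down (-0.19, 1 of 19 rose and 10 fell, 1 rose and 11 fell over the list alone, adjusted p = 0.0052). So were alveolar type 1 (-0.39, 3 of 11 fell, 1 rose and 4 fell over the list alone, adjusted p = 0.0099) and fibroblast markers (-0.41, 5 of 13 fell, also over the list alone, adjusted p = 0.0061). With the estimated correlation these were adjusted p = 0.36, 0.36, 0.60 and 0.36. Without Air animal 1 the means were -0.58 for endothelial and -0.53 for alveolar type 1 markers. In all, camera called 9 lists up and 4 down, and 0 held. Cell cycle means were higher on both slides that held both groups, by 1.08 and 1.32. Each of these slides held a single library per group, and Air animal 1 was on neither. In limma 5383 genes passed (3268 higher, 2115 lower; 1476 with a fold of at least 1.5), and 7716 without the libraries Air animal 1 and PEI 8.6 animal 61. With those libraries this was the highest count of the day 6 comparisons with air, and without them PEI 8.6 had the highest (7744).

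**Figure D2:**
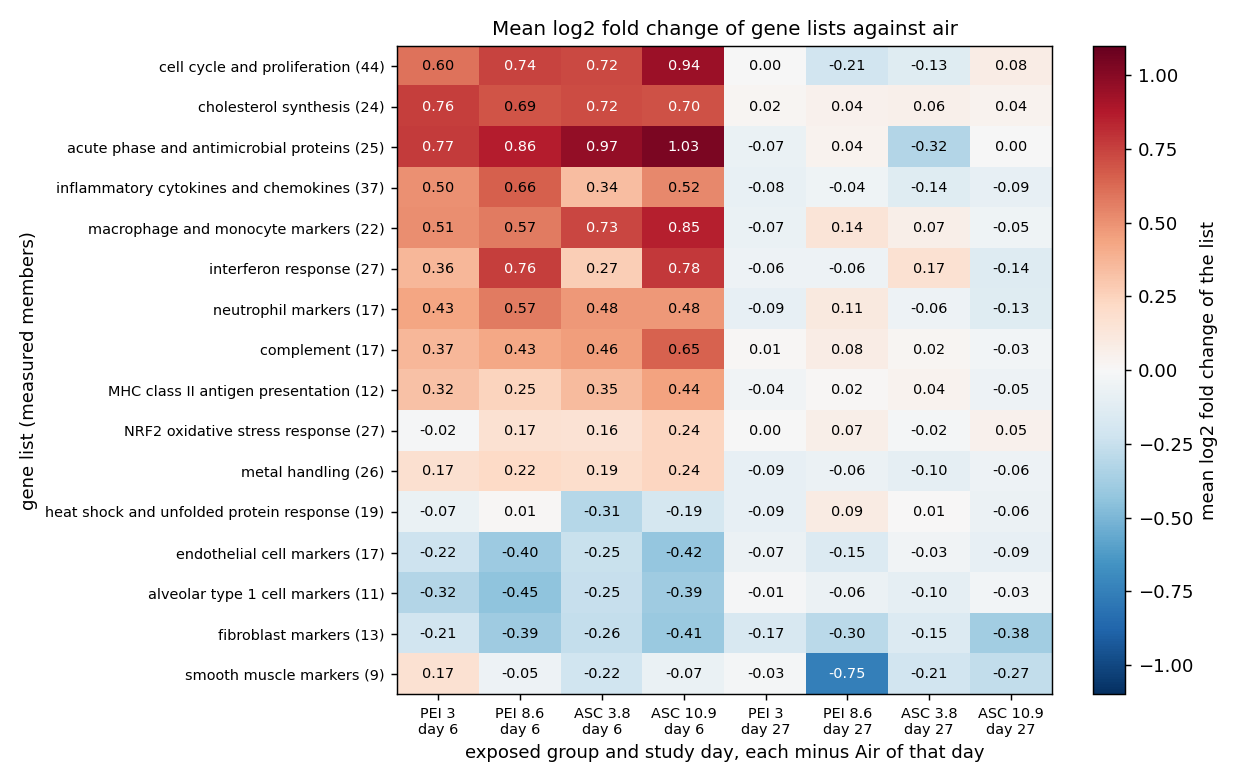
Mean log2 fold change (colour and printed values) of 16 gene lists, with their measured members in brackets, for each exposed group against air of the same day. Cell cycle means were 0.60 to 0.94 at day 6, while those of cholesterol synthesis were 0.69 to 0.76 at day 6 and 0.02 to 0.06 at day 27.

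Responses to the coatings at day 6 overlapped. Of the genes called at the higher doses, 1330 were higher with both PEI 8.6 and ASC 10.9, 685 were lower with both and 2 went opposite ways, where independent calls would share 291.2 and 107.3. At the lower doses 380 were higher and 98 lower with both coatings, and 0 went opposite ways, where independent calls would share 41.7 and 8.39. Log2 changes correlated across genes at r = 0.88 for the higher doses, against 0.50 in simulated groups that shared only their air animals, and genes are not independent replicates. With the air animals divided between the coatings, in 20 divisions, r was 0.70 in the median (0.48 to 0.81), and the shared genes numbered 32.5 higher (0 to 688) and 18.5 lower (0 to 303) in the median. At the lower doses r was 0.77, against 0.50 in the simulated groups. With the air animals divided it was 0.49 in the median (0.21 to 0.61), and 13.5 genes (0 to 172) were higher and 6 (0 to 55) lower with both. Fewer air animals per comparison also leave fewer calls. At day 27 the effects of PEI 8.6 and ASC 10.9 correlated at r = 0.10, below the 0.50 of the simulated groups, and at -0.11 in the median with the air animals divided (-0.42 to 0.21). The simulated groups held no differences in array brightness. Log2 Cy5 brightness differed from air of that day by 0.30 in PEI 8.6 and by -0.16 in ASC 10.9. Its share in the low correlation was not tested. With both, 17 genes were higher and 4 lower, where independent calls would share 0.793 and 0.205, but with the air animals divided the medians were 1 higher (1 to 3) and 0 lower (0 to 1).

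Air lungs of day 27 were compared with those of day 6 to see what time alone changed. In limma 0 genes passed, with 968 at an unadjusted p under 0.05. Cardiac muscle markers had a mean difference of 1.78 over 11 genes, with 0 rising, also over the list alone, and camera called the list up (adjusted p = 6.9e-07, and adjusted p = 0.43 with an estimated correlation). The list mean was 3.24 in Air animal 10 and 1.72 in Air animal 6 of day 27 but between -1.03 and 0.18 in the others, and the difference was 1.14 without Air animal 10. The array of Air animal 10 was the dimmest of all, with a median Cy5 signal of 115.5 and 62.1% of spots well above background. In all, camera called 8 lists up and 7 down between the air days, and 0 held. Without the libraries Air animal 1 and PEI 8.6 animal 61, 8 genes passed, and 5 passed without Air animal 1 alone.

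At day 27 the question was which changes remained after recovery. In PEI 3 lungs the clock repressor gene Nr1d1 (1.07 ± 0.19, n = 5 per group) and the pentose phosphate gene Taldo1 (0.38 ± 0.07) rose, and the lipid desaturase gene Scd fell (-1.67 ± 0.26). These 3 genes were all that passed in limma, 2 of them with a fold of at least 1.5. Of the 44 cell cycle genes and of the 24 cholesterol synthesis genes 0 passed, also over each list alone. Of 13 clock genes 1 rose (2 rose and 2 fell over the list alone), and camera did not call the list (adjusted p = 0.61, 0.99 with the estimated correlation). Camera called 2 lists down, cardiac muscle (mean -1.09, 0 of 11 called, also over the list alone, adjusted p = 0.022) and natural killer cell markers (-0.25, 0 of 14 called, also over the list alone, adjusted p = 0.0013). With the estimated correlation these were adjusted p = 0.99 and 0.99. The means were -0.45 for cardiac muscle without Air animal 10 and -0.14 for natural killer cell markers without Air animal 8. The count was 11 without the libraries Air animal 1 and PEI 8.6 animal 61, 1 without Air animal 6, Air animal 8 or PEI 3 animal 56, and 8 with only these groups in the model.

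In PEI 8.6 lungs at day 27, single receptor genes were higher than in air lungs. Sirpb3 rose by 1.34 ± 0.20, Trem1 by 1.16 ± 0.21, the fungal glucan receptor Clec7a by 1.12 ± 0.16, the scavenger receptor Olr1 by 1.00 ± 0.12 and the mannose receptor Mrc1 by 0.96 ± 0.17 (n = 5 per group), as did the cytokine gene Il18 (0.87 ± 0.14). Genes that were lower included Fbxl22 at -1.02 ± 0.20, the matrix protein Tnc at -0.90 ± 0.19 and the muscle filament gene Des at -0.89 ± 0.21. Of 9 smooth muscle markers 1 fell (8 adjusted over the list alone), with a list mean of -0.75; camera called it down at adjusted p = 9.8e-09, but adjusted p = 0.11 with an estimated correlation. Camera also called cardiac muscle (mean -1.37; 0 of 11 fell, 0 over the list alone), skeletal muscle (-0.47; 0 of 11, 1 over the list alone), club and goblet (-0.82; 0 of 13, 4 over the list alone) and fibroblast markers (-0.30; 0 of 13, 0 over the list alone) down, at adjusted p = 0.00084, 0.0013, 0.00096 and 0.0040. With an estimated correlation these were adjusted p = 0.68 for cardiac muscle and 0.29 for the others. Air animal 10 had a cardiac muscle mean of 3.24 and the dimmest array of all. Without that animal the means were -0.61 for smooth muscle, -0.73 for cardiac muscle, -0.27 for skeletal muscle, -0.60 for club and goblet and -0.25 for fibroblast markers. Called up were macrophage and monocyte markers (mean 0.14, 1 of 22 rose, also over the list alone, adjusted p = 0.014), macrophage lipid and lysosome genes (0.18, 0 of 28 called, also over the list alone, adjusted p = 0.00023) and heat shock genes (0.09, 0 of 19 called, 1 rose over the list alone, adjusted p = 0.010). The other lists called down were cell cycle (-0.21, 0 of 44 called, also over the list alone, adjusted p = 3.8e-06), B and plasma cell markers (-0.33, 0 of 10 called, 4 fell over the list alone, adjusted p = 0.00027) and matrix genes (-0.18, 1 of 29 fell, also over the list alone, adjusted p = 0.00081). With the estimated correlation these were adjusted p = 0.79, 0.29, 0.29, 0.78, 0.29 and 0.29. Without Air animal 10 the cell cycle mean was -0.12, and without PEI 8.6 animal 66 the heat shock mean was 0.05. In all, camera called 3 lists up and 8 down, and 0 held.

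Limma called 80 genes for PEI 8.6 at day 27 (64 higher, 16 lower; 51 with a fold of at least 1.5) and 153 without the libraries Air animal 1 and PEI 8.6 animal 61 of day 6, which enter this comparison through the shared variance alone. The count was 47, 46 and 41 without Air animals 8, 9 and 10, and 31, 30 and 41 without PEI 8.6 animals 62, 64 and 65.

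In ASC 3.8 lungs at day 27, clock genes were again among those called. Dbp rose by 3.57 ± 0.27 and Nr1d1 by 2.91 ± 0.19, and Bmal1 (2.73-fold lower) and Cry1 (-0.98 ± 0.14) fell, each in 5 of 5 animals. Mrc1 (0.75 ± 0.17) and Olr1 (0.72 ± 0.12) were higher here too. Of 13 clock genes 6 rose and 3 fell (7 and 3 adjusted over the list alone); camera called the list up at adjusted p = 2e-07, which held with an estimated correlation (adjusted p = 0.00025). Camera also called interferon (mean 0.17) and macrophage lipid and lysosome genes (0.10) up. It called cardiac muscle (-1.52), skeletal muscle (-0.45), club and goblet (-0.95), ciliated (-0.26) and B and plasma cell markers (-0.30) and cell cycle genes (-0.13) down. In these lists 0 genes were called, though over the list alone 4 of 13 club and goblet and 2 of 10 B and plasma cell markers fell. Adjusted p was 5.2e-05 to 0.028, and 0.27 to 0.84 with the estimated correlation. Without Air animal 10 the means were -0.88 for cardiac muscle, -0.24 for skeletal muscle, -0.73 for club and goblet, -0.11 for ciliated and -0.23 for B and plasma cell markers. For cell cycle genes it was -0.04 and for interferon genes 0.09. Limma called 48 genes (36 higher, 12 lower; 27 with a fold of at least 1.5), and about 1.1e+02 without the libraries Air animal 1 and PEI 8.6 animal 61. The count was 26 without ASC 3.8 animal L112, 30 without Air animal 10, and 82 with only these groups in the model.

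In ASC 10.9 lungs at day 27, Dbp (3.90 ± 0.27) and Nr1d1 (2.69 ± 0.19) rose and Bmal1 (-1.84 ± 0.13) fell, and so did Scd (-1.34 ± 0.26), the extracellular protein Spon2 (-1.23 ± 0.24) and the cell cycle inhibitor Cdkn2b (-1.04 ± 0.17). Dbp was higher on all 3 slides that held ASC 10.9 and air lungs, by 3.84 to 4.66. The clock list (6 rose, 3 fell; 8 and 3 over the list alone) was called up by camera at adjusted p = 2e-05 and adjusted p = 0.0025 with an estimated correlation. Of 29 matrix genes 4 fell (5 over the list alone), at camera adjusted p = 0.00022 and adjusted p = 0.42 with an estimated correlation. Camera also called fibroblast (mean -0.38, 1 of 13 fell, 2 fell over the list alone, adjusted p = 0.0021) and natural killer cell markers (-0.28, 0 of 14 called, also over the list alone, adjusted p = 0.020) down, the latter with a mean of -0.17 without Air animal 8. With the estimated correlation these were adjusted p = 0.29 and 0.97. Limma called 449 genes (221 higher, 228 lower; about 1.2e+02 with a fold of at least 1.5), and 1110 without the libraries Air animal 1 and PEI 8.6 animal 61. The count was 2175 without ASC 10.9 animal H120, 137, 159 and 263 without ASC 10.9 animals H118, H121 and H122, and 212, 138 and 192 without Air animals 6, 7 and 8. It was 939, 875 and 781 with scan day or slide as a fixed block or slide as a random block, and 74 with only these groups in the model.

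**Figure D3:**
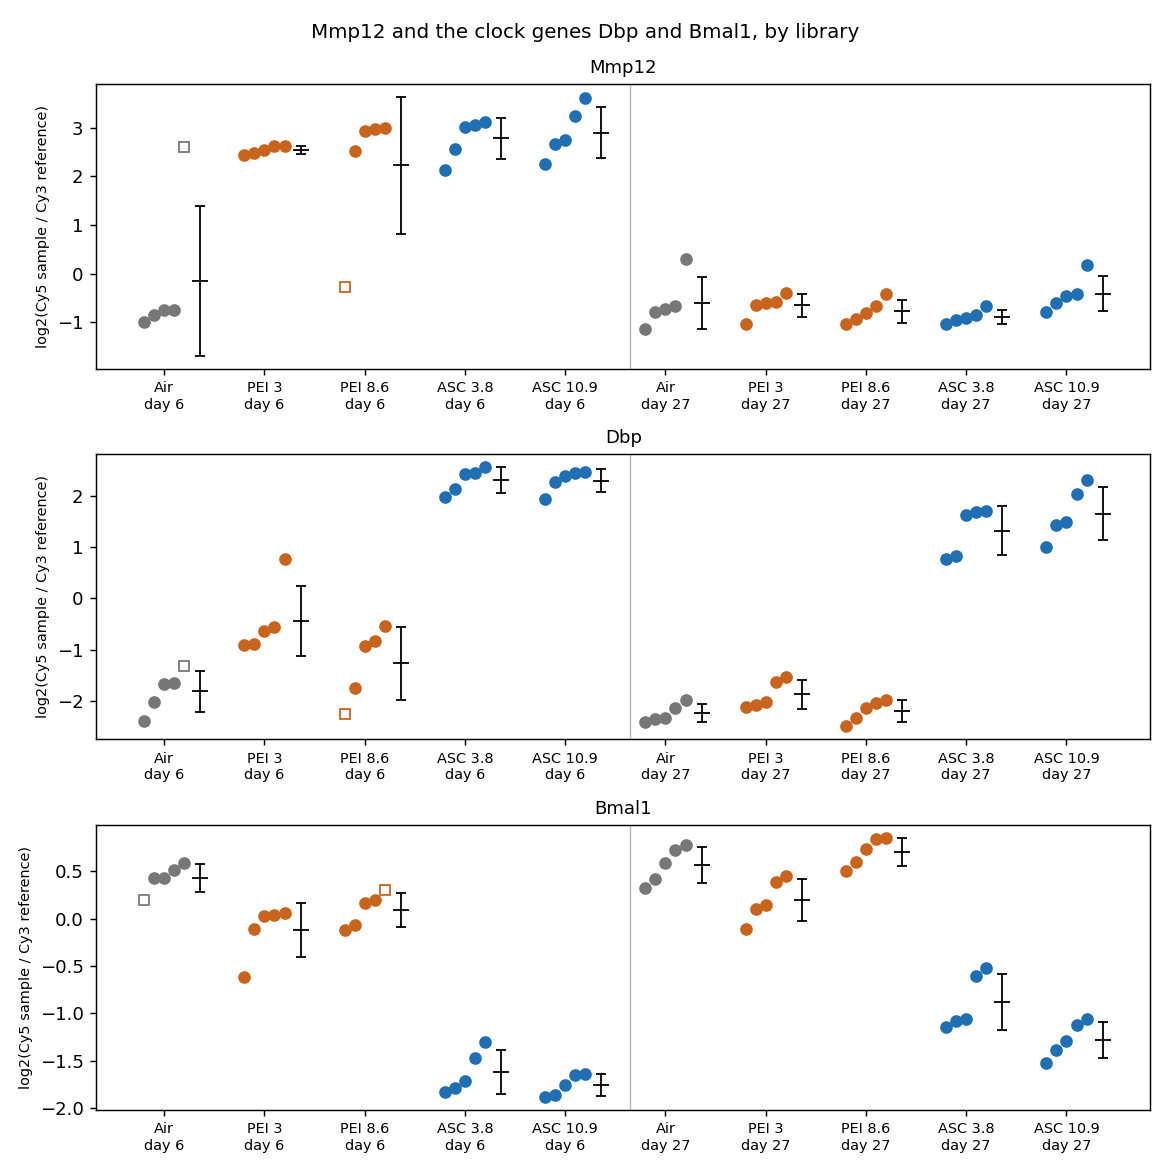
Log2 ratio of sample over reference (vertical axes) of Mmp12, Dbp and Bmal1 in each library by group and study day, with group means and SD as bars. Open squares are the libraries labelled Air animal 1 and PEI 8.6 animal 61; group means of Dbp were 2.30 in ASC 10.9 and -1.27 in PEI 8.6 at day 6.

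The coatings were compared directly to ask whether surface charge altered the response. The doses were near each other but not equal, and the time of collection is not known for any animal. A difference between these groups is therefore not one of the coating alone. At day 6, higher doses, Npas2 (4.01-fold), Bmal1 (1.85 ± 0.13) and Scd (1.62 ± 0.26) were higher with PEI 8.6 than with ASC 10.9, and Dbp (-3.57 ± 0.27), Tef (-1.78 ± 0.18) and Per2 (-1.69 ± 0.14) were lower. Of 13 clock genes 3 were higher and 6 lower (3 and 7 adjusted over the list alone), and of 19 heat shock genes 6 were higher (7, with 1 lower, over the list alone). Camera called the clock list at adjusted p = 1.9e-07 and the heat shock list at 3.2e-06, and both held with an estimated correlation (adjusted p = 0.00025 and 0.033). Dbp was lower with PEI on all 3 slides that held both groups, by -4.21 to -2.99. Mmp12 differed by -0.67 and was not called, and 0 of 44 cell cycle genes and 0 of 24 cholesterol synthesis genes were called, also over the lists alone. Camera nonetheless called the cell cycle list lower with PEI 8.6 (mean -0.20, adjusted p = 0.00047), and the mean was -0.05 without PEI 8.6 animal 61. It also called macrophage markers lower (mean -0.29; 0 of 22 called, 2 lower over the list alone; adjusted p = 0.00085), with -0.05 without that animal, and the glucocorticoid list (mean -0.55; 3 of 14 lower, 6 over the list alone; adjusted p = 9.9e-06). With an estimated correlation these were adjusted p = 0.86, 0.80 and 0.053. MHC class II, macrophage lipid and lysosome (0 genes called in both) and xenobiotic lists (3 of 20 lower, also over the list alone) were called lower and adipose markers (0 of 7 called) higher, and none of these held (adjusted p = 0.80, 0.80, 0.77 and 0.81). The adipose mean of 0.51 turned to -0.09 without PEI 8.6 animal 59. Without PEI 8.6 animal 61 the MHC class II mean went from -0.19 to -0.06 and the macrophage lipid and lysosome mean from -0.16 to -0.05. The xenobiotic mean of -0.23 ran from -0.36 to -0.10 without single animals. Limma called 250 genes (135 lower and the rest higher; 77 with a fold of at least 1.5), and 346 without the libraries Air animal 1 and PEI 8.6 animal 61, of which 181 were in both sets. The count was 136, 155 and 148 without ASC 10.9 animals H114, H115 and H116, and 32 with only these groups in the model.

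At the lower doses and day 6, Bmal1 (1.49 ± 0.13), Npas2 (2.72-fold) and Angptl4, a lipase inhibitor (1.75 ± 0.27), were higher with PEI 3 than with ASC 3.8. The neutrophil attractant Cxcl1 was higher as well (2.83-fold). Alb (-4.38 ± 1.00) and Ttr (-4.08 ± 0.94) were lower and Rup2 at least 12.4-fold lower, though Alb ranged from -6.25 to 0.05 among the ASC 3.8 lungs. These differences did not go with the coating. Day 6 means of Alb were -7.15 in PEI 3, -6.89 in PEI 8.6 and -7.10 in ASC 10.9, against -2.77 in ASC 3.8 and -4.06 in air. Ttr (-5.90 in ASC 10.9, -1.80 in ASC 3.8) and Rup2 (0.27 and 3.94) stood likewise. Of 19 heat shock genes 6 were higher (8, with 1 lower, over the list alone), and of 13 clock genes 2 were higher and 6 lower (3 and 8 over the list alone). Camera gave adjusted p = 2.7e-09 and 2.9e-06 for these lists, and both held with an estimated correlation (adjusted p = 0.0029 and 0.0013). Camera also called smooth muscle markers higher with PEI 3 (mean 0.39, and 0.24 without PEI 3 animal 48). It called macrophage (-0.22), natural killer cell (-0.29), alveolar type 2 (-0.20) and mesothelial markers (-0.42) and cell cycle genes (-0.13) lower, with 0 genes called in these lists, also over the lists alone. The cell cycle mean was -0.07 without ASC 3.8 animal L103 and -0.21 without ASC 3.8 animal L106. Also lower were NRF2 genes (-0.17, 0 of 27 called, 1 fell over the list alone, adjusted p = 0.00082), macrophage lipid and lysosome (-0.26, 1 of 28 rose and 1 fell, also over the list alone, adjusted p = 0.00037) and xenobiotic genes (-0.30, 3 of 20 fell, also over the list alone, adjusted p = 0.00055). Adjusted p for these 9 lists was 0.00037 to 0.030, and 0.092 to 0.87 with the estimated correlation. Limma called 210 genes (94 higher and the rest lower; 100 with a fold of at least 1.5), and 342 without the libraries Air animal 1 and PEI 8.6 animal 61. The count was 89 and 110 without ASC 3.8 animals L105 and L103, 124 and 139 without PEI 3 animals 47 and 48, fewer than 124 without PEI 3 animals 49 and 50, and 133 among genes detected on all arrays.

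At day 27, higher doses, Bmal1 (1.98 ± 0.13), Scd (1.41 ± 0.26) and Spon2 (1.19 ± 0.24) were higher with PEI 8.6 than with ASC 10.9, and Dbp (-3.86 ± 0.27), Nr1d1 (-3.04 ± 0.19) and Tef (-1.44 ± 0.18) were lower. Of 13 clock genes 3 were higher and 8 lower (3 and 8 over the list alone), at camera adjusted p = 0.0011 and adjusted p = 0.036 with an estimated correlation. Of 44 cell cycle genes 5 were lower (4 over the list alone), at camera adjusted p = 0.00044 and adjusted p = 0.98 with an estimated correlation. Arrays of these groups also differed in Cy5 brightness, by 0.46 on the log2 scale. Limma called 2849 genes (1303 higher, 1546 lower; 453 with a fold of at least 1.5), but 273 with brightness as a covariate, where Dbp stayed at -4.14 ± 0.26. Camera called 4 lists up and 3 down, and 1 held, the clock list.

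That count, for PEI 8.6 against ASC 10.9 at day 27, was 4501 without the libraries Air animal 1 and PEI 8.6 animal 61. It was 5529, 686, 961 and 1720 without ASC 10.9 animals H120, H121, H118 and H122, and 1285, 4391, 1431 and 995 without PEI 8.6 animals 62, 63, 64 and 66. Blocks gave 5137 (scan day), 5195 (slide, fixed) and 4359 (slide, random), and 130 genes passed with only these groups in the model.

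At the lower doses and day 27, the retinoic acid hydroxylase gene Cyp26b1 (1.29 ± 0.28), Bmal1 (1.08 ± 0.13) and Npas2 (0.85 ± 0.14) were higher with PEI 3 than with ASC 3.8, and Dbp (-3.20 ± 0.27), Nr1d1 (-1.84 ± 0.19) and Per2 (-0.82 ± 0.14) were lower. Cyp26b1 lost its call with slide or scan day as a block and with Agilent's processed signals. Of 13 clock genes 2 were higher and 6 lower (2 and 7 over the list alone), at camera adjusted p = 8.2e-06 and adjusted p = 0.0016 with an estimated correlation. Camera called 5 lists up and 5 down, and 1 held, the clock list. Limma called 18 genes (6 higher, 12 lower; 11 with a fold of at least 1.5), and 27 without the libraries Air animal 1 and PEI 8.6 animal 61. The count was 9 without ASC 3.8 animal L110 or L112 or PEI 3 animal 53 or 55, and 11 without PEI 3 animal 52 or 56. It was 10 among genes detected on all arrays or with Agilent's processed signals, and 11 with only these groups in the model or with the brightness covariate.

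Doses were compared within each coating at day 6. Between PEI 8.6 and PEI 3, limma called 0 genes (869 at an unadjusted p under 0.05), while 927 passed without the libraries Air animal 1 and PEI 8.6 animal 61 and 74 without PEI 8.6 animal 61 alone. Interferon response genes had a mean difference of 0.39 over 27 genes, with 0 called, also over the list alone; camera called the list up at adjusted p = 1.2e-06, and adjusted p = 0.62 with an estimated correlation. That mean was 0.22 without PEI 8.6 animal 59 and 0.65 without PEI 8.6 animal 61. In all, camera called 6 lists up and 5 down, and 0 held. Between ASC 10.9 and ASC 3.8, limma called 2 genes, the proline metabolism gene Prodh2 (-1.62 ± 0.30) and Scd (-1.36 ± 0.26), both lower at the higher dose and both with a fold of at least 1.5, and 180 genes without Air animal 1 and PEI 8.6 animal 61. Interferon genes had a mean difference of 0.51 there, with 0 of 27 called, also over the list alone, at camera adjusted p = 2.1e-10 and adjusted p = 0.50 with an estimated correlation. That mean ran from 0.35 to 0.68 without single animals, and camera called 6 lists up and 1 down, and 0 held. The count of 2 became 66 and 25 without ASC 3.8 animals L104 and L106, 0 without ASC 10.9 animal H114, H115 or H117 or ASC 3.8 animal L105 or L107, 48 with scan day as a block, 9 and 30 with slide as a fixed or random block, and 22 with only these groups in the model.

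Finally, each effect was tested for a difference between the days, as the exposed minus air difference at day 27 less that at day 6. For PEI 8.6, the signed effects of Mmp12 (-2.54 ± 0.63) and Prss30 (-3.97 ± 0.97) were lower at day 27. Those of Krt79 (2.62 ± 0.48) and Naaa (2.20 ± 0.40) were higher, since both genes lay below air at day 6 and above it at day 27. Group means of Krt79 were -1.76 in PEI 8.6 and -0.27 in air at day 6, and 1.18 and 0.05 at day 27. Those of Naaa were 0.57 and 1.91, then 2.89 and 2.03. Prss30 went the other way, with 2.50 and -0.40, then -1.35 and -0.28. Of 44 cell cycle genes 29 fell (41 adjusted over the list alone), and of 24 cholesterol synthesis genes 5 fell (19 over the list alone), at camera adjusted p = 1.7e-30 and 1.2e-10, and adjusted p = 0.38 and 0.52 with an estimated correlation. Camera called 6 lists up and 10 down, and 0 held. Limma called 379 genes (128 higher, 251 lower; 265 with a fold of at least 1.5), and 4851 without the libraries Air animal 1 and PEI 8.6 animal 61. The count was 2610 and 2337 without Air animal 1 or PEI 8.6 animal 61, and fewer than 133 without Air animals 2, 3 and 4 of day 6. It was 178, 200 and 130 without PEI 8.6 animals 57, 59 and 60, 133 without Air animal 10, and 150 and 250 without PEI 8.6 animals 64 and 65. It was 9 with only these groups in the model, 669 with slide as a random block, 217 with the Cy5 channel alone and 775 with the brightness covariate.

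For ASC 10.9, the signed effects of Lcn2 (-6.22 ± 1.87), Ccl12 (-3.19 ± 0.86) and Chi3l1, a chitinase-like protein (-3.12 ± 0.70), were lower at day 27 than at day 6. Those of Krt79 (2.97 ± 0.48) and Pla2g2d (2.73 ± 0.42) were higher, since both genes lay below air at day 6 and above it at day 27. Group means of Krt79 were -2.26 in ASC 10.9 and -0.27 in air at day 6, and 1.03 and 0.05 at day 27. Those of Pla2g2d were 0.50 and 2.55, then 3.44 and 2.76. Chi3l1 lost this call with Agilent's processed signals. Of 44 cell cycle genes 27 fell (34 over the list alone), of 24 cholesterol synthesis genes 12 (15 over the list alone) and of 22 macrophage markers 9 (13 over the list alone). Camera gave adjusted p = 1.9e-13, 6.2e-07 and 3.1e-06 for these lists, and adjusted p = 0.68 for each with an estimated correlation. Camera called 0 lists up and 9 down, and 0 held. Limma called 3454 genes (1330 higher, 2124 lower; 1640 with a fold of at least 1.5), and 6161 without the libraries Air animal 1 and PEI 8.6 animal 61. The count was 5482 and 1494 without Air animals 1 and 5 of day 6, 2276 without Air animal 7, 2294 without ASC 10.9 animal H114 and 2178 without ASC 10.9 animal H118. It was 961 with the brightness covariate and 1988 with only these groups in the model.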

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

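Chosen only after the result was seen were the tests of a label exchange, of the array of PEI 8.6 animal 61 and of an inflamed air animal, every test on the clock genes, the tests of slide and of a coating difference at day 27, and the fits without 2 libraries and with a brightness covariate.

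Gaps between the extreme animal of a group and its nearest neighbour, divided by the group's range, were set against Dixon's critical value of 0.71. They exceeded it in 30 of 150 pairs of a group and a measure, where chance alone gives about 7.5. The pairs are not independent, since the same libraries enter every measure and a single library can be counted many times. The library labelled Air animal 1 of day 6 was the extreme one on the first component (0.768), on the list means of cell cycle (0.786), cholesterol synthesis (0.847), acute phase (0.743), cytokine (0.934), macrophage (0.763), interferon (0.884), neutrophil (0.720) and complement genes (0.755), all highest, and on endothelial (0.745) and alveolar type 1 markers (0.776), both lowest. The library labelled PEI 8.6 animal 61 of day 6 was the lowest of its group on the first component (0.775), acute phase (0.771) and complement genes (0.7703), and the highest on endothelial (0.810) and alveolar type 1 markers (0.798).

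A first pattern to weigh is that these libraries stood with the other group. Projected on the PEI 8.6 effect of the other 8 libraries, Air animal 1 had a slope of 0.951, within the range of the other PEI 8.6 libraries (0.736 to 1.02), and PEI 8.6 animal 61 had one of -0.0199, just below the other air libraries (0.027 to 0.114), so an exchange of the labels is a candidate explanation with the partner it needs. Against faulty arrays, the deviation of Air animal 1 from the other air libraries correlated at r = 0.795 across genes with the difference between ASC 10.9 at day 6 and air at day 27, which shares no library with it. The array of PEI 8.6 animal 61 was the dimmest of its group (median Cy5 signal 128, against 218 to 322). The deviation of that library from the rest of its group correlated at r = -0.598 with the slope of genes on brightness in the 8 other groups, as dimness would give, so dimness as part of it stays open. As the whole of it, a faulty or dim array is argued against by r = 0.792 with the difference between air at day 27 and ASC 10.9 at day 6 once that slope was taken out (0.757 before). An air animal with lung inflammation beside an exposed animal that did not respond cannot be told apart from an exchange by these values (slope -0.0199), since either gives the same profiles. The labels were not changed.

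A second pattern is the difference of clock genes between ASC lungs and the rest. PEI 3 lungs moved the same way by less, with Dbp 2.58-fold higher and Bmal1 at -0.56 ± 0.13 at day 6 and Nr1d1 at 1.07 ± 0.19 at day 27. In PEI 8.6 lungs only Tef was called (-0.61 ± 0.18 at day 6), opposite to its direction in ASC lungs. Its day 6 means were 0.72 in PEI 8.6, 1.33 in air, 2.61 in ASC 3.8 and 2.50 in ASC 10.9. Against an effect of slides, Dbp was higher in ASC lungs than in others on all 7 slides, by 2.88 or more. Against lung inflammation as the whole cause, the Dbp difference between PEI 8.6 and ASC 10.9 lungs was -3.57 at day 6, although inflammatory genes rose in both. Over the 13 clock genes the ASC 10.9 effect at day 27 had a slope of 0.898 on that at day 6, against 0.0315 over 5373 other genes, which is consistent with another time of day of collection for the ASC animals; the labels give no clock time. An effect of the coating itself, with a difference between ASC doses of -0.0123 for Dbp at day 6, cannot be told apart from it. Every ASC animal had the coating, and the time of collection is not known for any animal.

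The last pattern is the count of 2849 genes between PEI 8.6 and ASC 10.9 at day 27. Brightness of the arrays is a candidate cause, since the difference correlated at r = 0.643 across genes with the slope on Cy5 brightness within the 8 other groups. With brightness as a covariate 273 genes passed, 265 of them also called before, and the median size of the log2 change went from 0.385 to 0.237 and the median SE from 0.111 to 0.0965, so the calls ended by smaller changes and not by a wider error. Slide as the cause is argued against by a count of 5195 with slide as a block. A difference between the coatings cannot be told apart from brightness for the remaining genes, because the brightness of the arrays goes with the group (0.46 on the log2 scale).

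Other animals far from their groups were these. Cardiac muscle markers were highest in ASC 10.9 animal H113 (0.929), ASC 3.8 animal L111 (0.946), PEI 3 animals 54 (0.878) and 48 (0.902) and PEI 8.6 animal 59 (0.859). ASC 10.9 animal H113 was lowest for macrophage (0.758) and neutrophil markers (0.902). PEI 3 animal 49 was highest for acute phase genes (0.845), PEI 3 animal 51 lowest for neutrophil markers (0.722) and PEI 3 animal 56 lowest for cytokine genes (0.769). At day 27, ASC 3.8 animal L111 was highest for cell cycle genes (0.842), ASC 3.8 animal L109 lowest for macrophage markers (0.845), PEI 8.6 animal 62 lowest for endothelial markers (0.847) and Air animal 6 highest for clock genes (0.765).

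By a test of the difference, PEI and ASC groups differed in 250 genes (higher doses) and 210 (lower doses) at day 6. At day 27 they differed in 2849 and 18. These groups also differ in dose, and the time of collection, not known for any animal, may differ between the coatings for every gene. The counts are therefore not those of the coating alone. The exposure effect differed between the days in 379 genes for PEI 8.6 and 3454 for ASC 10.9.

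For each count, 100 splits of the same animals were compared, the real one included. At day 6 against air, chance cannot be excluded for PEI 3 (566 genes, 6 splits as large, highest other 3417) and PEI 8.6 (2494, 15 splits, highest other 8919). The share was under 0.05 for ASC 3.8 (2830, 3 splits, highest other 5391) and ASC 10.9 (5383, 3 splits, highest other 5962), though other splits gave more genes. Every one of the larger splits for PEI 3, ASC 3.8 and ASC 10.9 moved Air animal 1, and all of those for PEI 8.6 moved Air animal 1, PEI 8.6 animal 61 or both; the highest exchanged just these. Counts several times the real one point to a structure of the samples that the labels do not give. The share thus depends on where these libraries stand, so it decides nothing about chance for the day 6 counts against air. One such split for PEI 8.6 (4495 genes) put no slide and no scan day on both sides; its blocked value cannot be had for that reason, and the real split gave within-slide values in the report.

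At day 27 against air, no other split drawn gave as many genes for PEI 3 (3 genes, 1 split, highest other 1), PEI 8.6 (80, 1 split, highest other 12) and ASC 3.8 (48, 1 split, highest other 5). For ASC 10.9 the share was under 0.05 (449, 3 splits, highest other 1342), though other splits gave more genes. No other split drawn gave as many for PEI 8.6 against ASC 10.9 at day 6 (250, 1 split, highest other 85). Nor did any for PEI 3 against ASC 3.8 at day 6 (210, 1 split, highest other 24) and day 27 (18, 1 split, highest other 2). For PEI 8.6 against ASC 10.9 at day 27 the share was under 0.05 (2849, 4 splits, highest other 7047). Other splits gave more genes there, so chance is not excluded. The split of 7047 genes exchanged PEI 8.6 animal 63 with ASC 10.9 animal H120 and had a brightness difference of 0.70, against 0.46 for the real one, and the split of 1342 genes one of -0.62 against -0.16. Between the ASC doses the share was under 0.05 (2 genes, 3 splits, highest other 2), but other splits gave as many genes, so chance is not excluded. Between the PEI doses (highest other 860) and the air days (highest other 216) 0 genes were called, which all 100 splits reach by construction, so splits decide nothing there. For the days, chance cannot be excluded for PEI 8.6 (379, 13 splits, highest other 5168). The share was under 0.05 for ASC 10.9 (3454, 2 splits, highest other 3702), though another split gave more genes.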

How the results depend on the processing

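The fits without 2 libraries and with a brightness covariate were chosen after the results were seen; all other alternatives were planned. No paired analysis was possible because animal numbers do not recur between groups. Of 255 counts under alternatives other than the omission of single animals and Aquantile scaling, which changes no ratio, 170 lay within 1.5 times the count reported and 85 did not. The cause was not tested, except where fewer animals or a fold threshold leave fewer calls by construction, and probes near background limit what any setting can show. Named genes kept their direction in the fits that followed them but for 3 values with Agilent's processed signals; as alternatives, array weights, the Cy5 channel alone and every probe kept were run for counts only, and the brightness covariate for counts and, between PEI 8.6 and ASC 10.9 at day 27 alone, for gene changes.

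Counts are given in the order PEI 3, PEI 8.6, ASC 3.8, ASC 10.9 against air at day 6, then the same at day 27. Without Air animal 1 and PEI 8.6 animal 61 they were 4349, 7744 and 6037 at day 6 (ASC 10.9 within 1.5 times) and 11, 153, 1.1e+02 and 1110 at day 27; for the coatings 342 (lower doses, day 6) and 4501 (higher doses, day 27); for the doses 927 (PEI) and 180 (ASC); for the days 4851 (PEI 8.6), 6161 (ASC 10.9) and 8 (air). With array weights, which were lowest for those same libraries (0.124 at the lowest), they were 5259, 7395, 6843 and 8612 at day 6 and 1.1e+02, 236, 154 and 3894 at day 27; for the coatings 837 and 525 at day 6 and 382 and 6975 at day 27, lower doses first; for the doses 426 and 542; for the days 4778, 7371 and 14.

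With a fold of at least 1.5 the counts were 243, 694, 684 and 1476 at day 6, 51, 27 and 1.2e+02 for PEI 8.6, ASC 3.8 and ASC 10.9 at day 27, 100, 77, 11 and 453 for the coatings and 1640 for the days with ASC 10.9. With only the compared groups in the fit they were 0, 0 and 935 at day 6 (PEI 3, PEI 8.6, ASC 3.8), 8, 82 and 74 at day 27 (PEI 3, ASC 3.8, ASC 10.9), 32 at day 6 (higher doses) and 11 and 130 at day 27 for the coatings, 22 for the ASC doses, and 9, 1988 and 3 for the days. With slide as a fixed block they were 5 (PEI 3, day 27), 875 (ASC 10.9, day 27), 5195 (coatings, higher doses, day 27) and 9 (ASC doses). With slide as a random block, correlation 0.108, they were 781, 4359 and 30 for the last of these, and 669 for the days with PEI 8.6. With scan day as a block they were 895 (PEI 3, day 6), 939 (ASC 10.9, day 27), 5137 (coatings, higher doses, day 27) and 48 (ASC doses).

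Agilent's processed signals gave 8 (PEI 3, day 27), 10 (coatings, lower doses, day 27) and 2 (air days). The Cy5 channel alone gave 7 (PEI 3, day 27), 6 (ASC doses), 217 (PEI 8.6 days) and 2 (air days). The brightness covariate gave 8 (PEI 3, day 27), 11 and 273 (coatings, day 27), 6 (ASC doses), 775 and 961 (days). Genes detected on all 50 arrays gave 133 and 10 for the coatings at lower doses, every probe kept gave 4 and no filter 0 for the ASC doses.

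Leaving out each animal in turn gave 129 to 3429, 850 to 6111, 1674 to 5302 and 3681 to 7231 at day 6, and 1 to 4, 30 to 1.1e+02, 26 to 44 and 137 to 2175 at day 27. For the coatings it gave 89 to 203 and 136 to 276 at day 6 and 9 to 16 and 686 to 5529 at day 27, for the doses 0 to 74 and 0 to 66, and for the days 1.0e+02 to 2610, 1494 to 5482 and 0 to 5. In the comparisons with air the highest value at day 6 came without Air animal 1, or for PEI 8.6 without PEI 8.6 animal 61.

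Some signs reversed. With Agilent's processed signals Lamp3 (PEI 8.6, day 6) was -0.011, Chia (ASC 3.8, day 6) -0.023 and C1qc (ASC 10.9 days) 0.44. Among genes detected on all arrays the mean of the glucocorticoid list was 0.0031 (PEI 3, day 6) and -0.013 (PEI 8.6 days). Without the 2 libraries it was 0.056 and -0.16, the cholesterol list was 0.14 between the PEI doses, and for air days the cytokine list was 0.048, acute phase 0.072, complement 0.026, cholesterol 0.018 and endothelial -0.039. Leaving out each animal in turn, the glucocorticoid list ran from -0.13 to 0.063 (PEI 3, day 6) and from -0.075 to 0.13 (PEI 8.6 days), and the adipose list (coatings, higher doses, day 6) from -0.087 to 0.78. The cholesterol list between the PEI doses ran from -0.16 to 0.14. For air days the ranges were -0.28 to 0.048 (cytokine), -0.36 to 0.072 (acute phase), -0.28 to 0.026 (complement), -0.24 to 0.018 (cholesterol) and -0.039 to 0.21 (endothelial), each crossing 0 only without Air animal 1.

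Of 720 named values, calls were lost for 6 without the 2 libraries, 80 with Agilent's processed signals, 27 with the deposited table, 57 with slide as a fixed block, 39 with scan day as a block, 89 with no filter and 388 with only the compared groups. Of 177 list calls, 169 were lost with an estimated correlation, 37 with Agilent's processed signals and 22 without the 2 libraries, and 69 held with fry.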

Other observations

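The single-library ranges and the genes picked from lists in this part were chosen only after their values were seen, while the list tests were planned.

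Some transcripts varied widely between animals of a group. Lcn2 had log2 ratios from 6.43 to 6.94 in ASC 10.9 lungs of day 6, but from 0.43 to 6.36 in ASC 3.8 lungs and from -0.47 to 6.79 in PEI 8.6 lungs of that day. The defensin gene Defb5 lay between 4.83 and 5.80 in PEI 3 lungs of day 6, and between 1.19 and 6.03 in ASC 3.8 lungs. Alb, a liver transcript, ranged from -6.66 to -1.90 in air lungs of day 6 and from -6.25 to 0.05 in ASC 3.8 lungs, while it lay between -7.42 and -6.91 in PEI 3 lungs. Mean cardiac muscle markers were highest in Air animal 10 of day 27, at 3.24 on the log2 ratio scale.

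Among 13 club and goblet cell markers 6 rose with ASC 10.9 at day 6 (6 over the list alone; camera adjusted p = 0.086, and adjusted p = 0.60 with an estimated correlation), with Agr2 at 1.54 ± 0.45 and Spdef at 0.57 ± 0.16. Of 15 T cell markers 2 rose in the same comparison (2 over the list alone; camera adjusted p = 0.29, and adjusted p = 0.74 with an estimated correlation), Icos by 0.52 ± 0.14. Of 10 B and plasma cell markers 1 rose and 2 fell (the same over the list alone; camera adjusted p = 0.25, and adjusted p = 0.69 with an estimated correlation): Derl3 rose by 0.58 ± 0.21 while Fcrla (-0.89 ± 0.21) and Pou2af1 (-0.85 ± 0.20) fell.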
